A study of Homo sapiens with 15 samples.

How the data were processed

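RNA-seq of A549 cells was analysed in 15 libraries, 5 groups of 3: untreated, IL4, IL4 with Compound A, IL4 with control siRNA and IL4 with ALOX15 siRNA. The deposited table holds expected counts, the estimated read counts per gene that RSEM returns, with 1 column per library and no scaling. Per the submitters' processing notes, the authors aligned the reads with Bowtie2 2.1.0 and quantified them with RSEM 1.2.15 on the hg38 genome. The gene annotation, read filters and strand setting were not given in the sources used here. The table holds 26475 genes, of which 7860 had no count in any library. Of the values, 3.63% to 4.19% per library were not whole, as arises where reads are shared between genes, and named genes with such counts in 4 or more libraries are marked, as is ALOX15.

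Counts were rounded and filtered with edgeR's filterByExpr, which left 12795 genes holding 99.87% or more of every library's counts. Totals ran from 6407936 to 11031246 with a median of 7442934. Libraries were scaled by TMM and fitted together by edgeR 4.0.16 (robust quasi-likelihood, 1 coefficient per group) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. The common biological coefficient of variation was 0.0731. The SE of a log2 change was taken as its absolute size divided by the square root of the F statistic. Counts per 1e6 counts (CPM) are given as group means with SD, and a prior count of 2 was used for log2 CPM. For genes with 1 to 3 counts in a group, the ratio of summed counts is given with an exact 95% interval.

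The comparisons were IL4 against untreated, Compound A against IL4, ALOX15 siRNA against control siRNA, control siRNA against IL4, and the difference between the Compound A and ALOX15 siRNA effects. Overlaps were counted by direction and set beside the number expected of independent lists, n1 x n2 / N by direction. That number takes every gene as equally likely to be called, so an excess over it need not mean a shared response. The effect of the IL4 libraries shared by 2 comparisons was simulated 20 times with unchanged groups. A set of 19 gene lists was tested with camera (limma 3.58.1) with an inter-gene correlation preset to 0.01, adjusted over the 76 tests of 19 lists and 4 comparisons, and again with an estimated correlation. Members were counted by their adjustment over all genes and by one over the list alone. The lists were IL-4/STAT6 response, eicosanoid and oxylipin metabolism, cholesterol synthesis and uptake, fatty acid synthesis and desaturation, liver X receptor targets, PPAR targets and fatty acid oxidation, NRF2 targets, and ferroptosis and lipid peroxide handling. The others were aryl hydrocarbon receptor and xenobiotic response, type I interferon response, NF-kB and acute inflammation, cell cycle, unfolded protein and integrated stress response, p53 targets, hypoxia and glycolysis, epithelial-mesenchymal transition and matrix, mucin and goblet cell genes, alveolar epithelial genes, and markers of other cell types.

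The comparisons, tests, lists, most other settings tried and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison, the 10 highest and 10 lowest log2 changes among genes that passed, had a mean of at least 1 CPM in a group and did not overlap between the groups' libraries. It also took 5 in each direction for the difference, 14 fixed genes, up to 4 members of each list and up to 8 genes of each overlap. Genes named outside the rule were chosen after their values were seen. They are SCD, INSIG1, SLC26A2 and PLA2G4A where Compound A is concerned, and those said to be so in the closing section. Gene coordinates came from GENCODE gene models on GRCh38, matched by symbol.

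The fit was tested on simulated data with the libraries' depths and gene-wise dispersions, in which 200 of 12795 genes were changed. Changes of log2 1 were recovered in 86.6%, 82.1%, 80.6% and 85.1% of cases in the 4 pairwise comparisons, in the order given above, and changes of log2 0.5 in 43.3%, 58.2%, 59.7% and 64.2%. False calls made up 3.21% to 5.23% of all calls. These simulated counts held no GC content trend between libraries and no library that stood apart, so the rates may not hold for the real ones. Other settings, chosen at the same time, were RLE and upper-quartile scaling, no filter, a stricter filter (1 CPM in 3 libraries), unrounded counts, DESeq2 1.42.0, a fit of the compared groups only, a replicate block, a 2-fold threshold, and each library left out in turn. Added after the data were seen were a correction of each library's trend on transcript GC content (loess span 0.3, with a GC value for 95.1% of tested genes), Compound A against control siRNA with and without IL4 replicate 1 in the fit, libraries of other groups left out, list tests of the difference, and list tests without ALOX15. No library was left out of the reported fit.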

Results

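RNA was sequenced from A549 cells, an epithelial line derived from a human lung adenocarcinoma, in 5 groups of 3 libraries. One group was untreated and the other 4 received 10 ng/ml interleukin-4 (IL4), a cytokine of type 2 immunity. Of these 4, one had IL4 alone, one had an added substance named only as Compound A, one had a control siRNA and one had a pooled siRNA against ALOX15 at 1 uM. The labels give a time of 48 h. ALOX15 encodes arachidonate 15-lipoxygenase, an enzyme that adds oxygen to polyunsaturated fatty acids. The dose and nature of Compound A and the dose of the control siRNA were not given in the sources used here.

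The estimated counts summed to 11031246, 9083233 and 6694576 in untreated replicates 1, 2 and 3, and to 7108429, 7572350 and 7728912 with IL4 alone. They summed to 8479489, 9526975 and 6742984 with Compound A, to 6916904, 6407936 and 7028749 with control siRNA, and to 7442934, 6455431 and 7762937 with ALOX15 siRNA. Ribosomal RNA genes took between 0.683% and 2.52% of the counts. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of replicates was as close as counting noise alone: the chi-square per degree of freedom was lowest, 1.60, between untreated replicates 2 and 3. It was highest between IL4 replicate 1 and its group mates, at 10.0 against replicate 2 and 13.5 against replicate 3. On the principal components of log2 CPM (counts per 1e6 counts), the untreated libraries lay at -36.5 to -35.3 on component 1 and all IL4-treated ones at 5.65 or above. IL4 replicate 1 stood apart on component 2, at 34.4, while the Compound A libraries lay at -21.2 to -14.9 on that component.

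**Figure D1:**
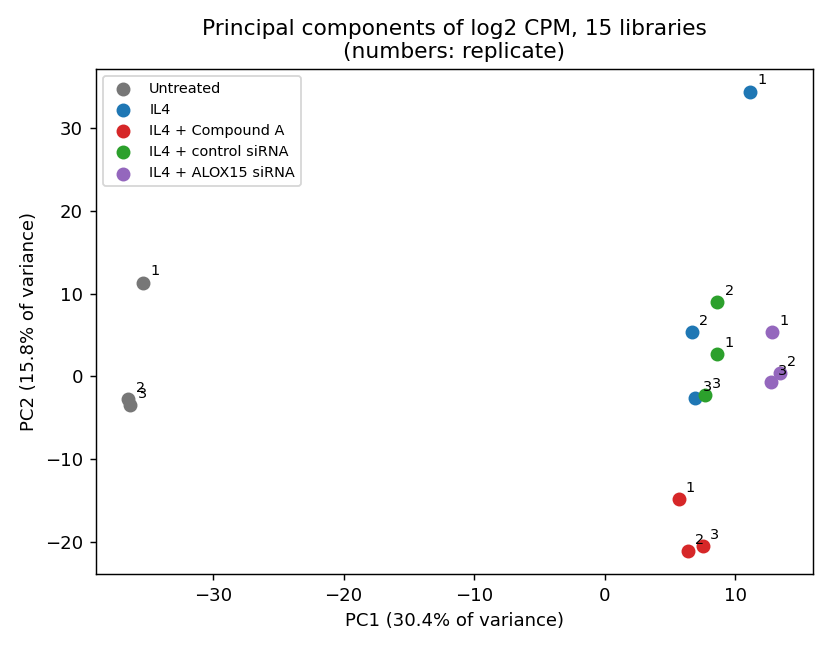
Each point is 1 library, coloured by group, placed by its scores on principal components 1 and 2 of log2 CPM (arbitrary units). Component 1 separates the 3 untreated libraries, all below -35.3, from the IL4-treated ones, and IL4 replicate 1 lies at 34.4 on component 2.

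ALOX15, the gene the siRNA was aimed at (ENSG00000161905.12, minus strand of chromosome 17, 4630902 to 4642294 of GRCh38), was nearly silent without IL4. Its level in untreated replicates 1, 2 and 3 was 0, 0.110 and 0.299 CPM, and with IL4 it was 6.00, 4.72 and 5.09 CPM. With Compound A it was 2.59, 2.23 and 1.81 CPM, with control siRNA 3.91, 3.56 and 3.28 CPM, and with ALOX15 siRNA 0.136, 0.314 and 0.259 CPM. Its counts were not whole in replicate 3 of both siRNA groups, 22.78 and 2.47, so part of them may belong to another gene. The group means were 0.136 ± 0.151, 5.27 ± 0.661, 2.21 ± 0.388, 3.58 ± 0.313 and 0.236 ± 0.0911 CPM (SD, n = 3 each). Since the untreated libraries together held 3 ALOX15 counts against 119 with IL4, the rise is given as a ratio of 47.2 with a 95% counting interval of 15.8 to 232. Such intervals cover counting error only. The siRNA lowered it by 3.85 on the log2 scale (SE 0.43, adjusted p = 8.5e-05), a 14.4-fold decrease against control siRNA. Compound A lowered it by a log2 change of -1.23 (SE 0.25, adjusted p = 0.0033) against IL4 alone. Set against control siRNA, Compound A gave -0.68 and did not pass (adjusted p = 0.16). Control siRNA itself gave -0.55 against IL4 alone (SE 0.24, adjusted p = 0.898). The direction in each library matched its label.

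**Figure D2:**
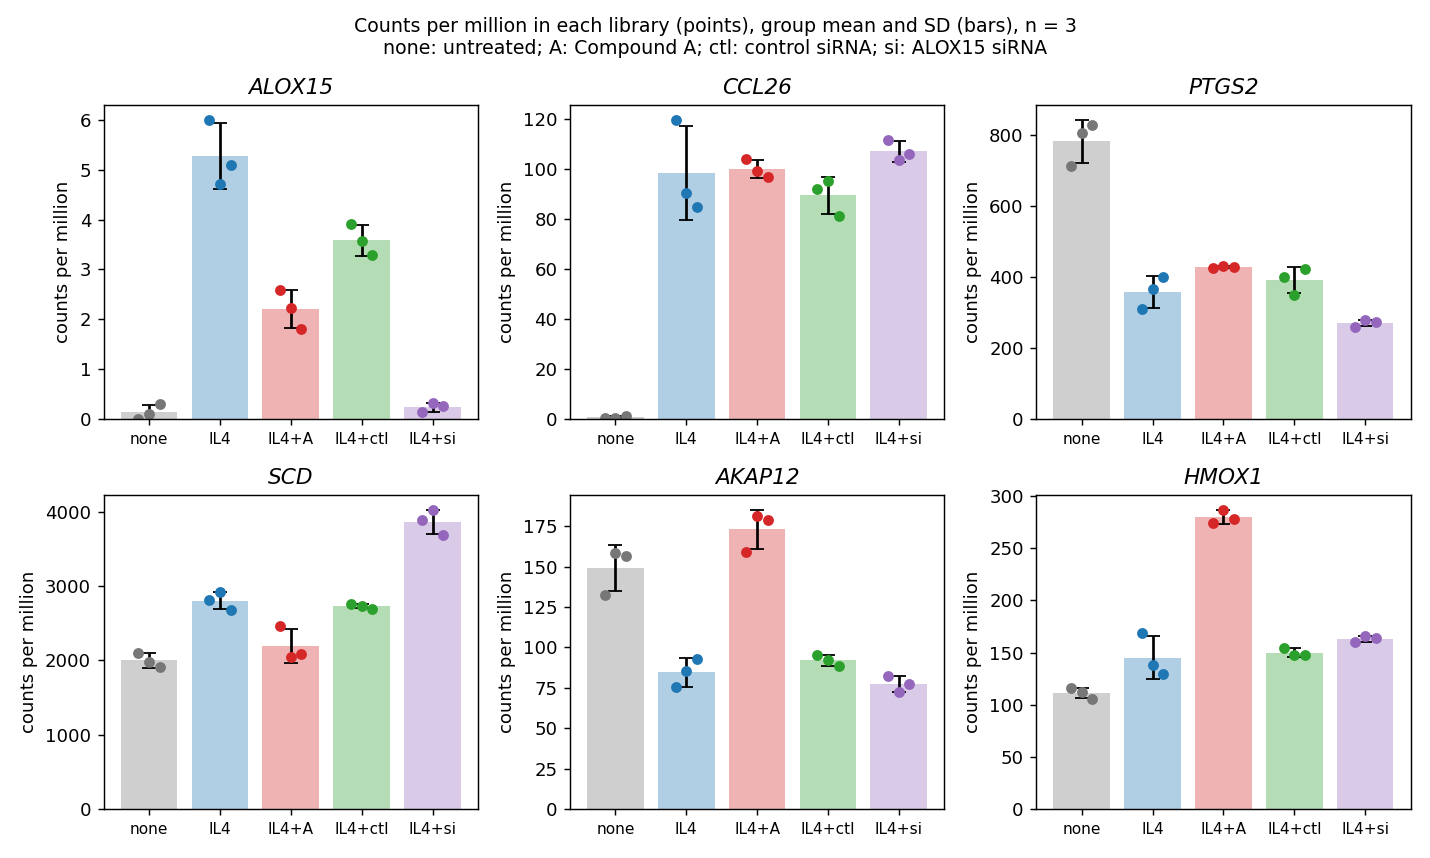
CPM of 6 genes in each library (points), with the group mean (bars from 0) and SD (error bars), n = 3 per group. ALOX15 averages 5.27 CPM with IL4 and 0.236 CPM with ALOX15 siRNA, while HMOX1 is highest with Compound A.

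What IL4 alone did to these cells was asked first. CCL26 (chromosome 7, 75769533 to 75789896), which encodes the eosinophil attractant eotaxin-3, rose from 0.841 ± 0.438 to 98.3 ± 18.8 CPM (SD, n = 3), 123-fold (log2 6.94, SE 0.20, adjusted p = 3.7e-15). CISH, a feedback inhibitor of cytokine signalling, rose 25.5-fold. DUOX2, which makes hydrogen peroxide at epithelial surfaces, had 303 counts with IL4 and 1 without, a ratio of 361 with a 95% counting interval of 64.3 to 14294. Its counts were not whole in 4 libraries, so part of them may belong to a related gene. ITLN1, a secreted lectin of goblet cells, had a ratio of 171 (30.3 to 6817) and CCL24, a second eosinophil attractant, one of 35.1 (9.30 to 297). PTGS2, the inducible cyclooxygenase, fell from 782 ± 61.3 to 358 ± 46.3 CPM, and PLA2G4A, the phospholipase that releases arachidonic acid, fell from 238 ± 5.92 to 114 ± 7.36 CPM.

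Further genes named by the fixed rule also had few counts without IL4. FAM26E had a ratio of 90.5 (95% counting interval 24.6 to 754), KRT16, a stress keratin, one of 32.9 (10.9 to 163), SMPD3, a sphingomyelinase, one of 33.3 (5.51 to 1363) and PIGR, the transporter of polymeric immunoglobulins, one of 16.1 (4.04 to 139). The antisense transcript SLC26A4-AS1 had a ratio of 164 (29 to 6535) and is uncertain, because the counting was not stated to use strand. Among the genes that fell most were CNTNAP2, a neuronal adhesion protein, with a log2 change of -3.09 (SE 0.31), and SLC51B, a subunit of a bile acid transporter, with -2.07 (SE 0.26). C9orf152 changed by -1.89 (SE 0.21), and CA9, a hypoxia-induced carbonic anhydrase, by -1.98 (SE 0.32). The genes of the receptor and its signalling factor did not pass: IL4R had a log2 change of 0.31 (SE 0.14, adjusted p = 0.12), IL13RA1 of 0.04 and STAT6 of 0.06. The gel-forming mucin gene MUC5AC had -0.33 (SE 0.16, adjusted p = 0.16). ALOX15B, IL13RA2, SOCS1 and POSTN had too few counts to be tested.

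Of the 20 measured genes of the IL-4/STAT6 list, 12 rose and 1 fell, and adjusted over the list alone 14 rose and 3 fell (camera adjusted p = 4.2e-09, and adjusted p = 0.036 with an estimated correlation). Type I interferon genes rose in 18 of 34 cases and fell in 1, with the same counts adjusted over the list alone (adjusted p = 9.6e-07, and adjusted p = 0.0084 with an estimated correlation). They included the transcription factor IRF1, 2.41-fold up, and TRIM22, 2.41-fold up. In the list of epithelial-mesenchymal transition and matrix genes, 22 of 39 rose and 3 fell, or 25 and 3 adjusted over the list alone (adjusted p = 8.3e-12, and adjusted p = 0.0084 with an estimated correlation). The matrix glycoprotein TNC rose 6.26-fold, the collagen COL5A1 4.82-fold and COL1A1 2.72-fold. COL1A1 is also 1 of the 6 measured markers of other cell types, of which 3 rose and 1 fell by either adjustment (adjusted p = 0.19). Counts of passing members with 1 library left out were added after the data were seen: in the IL-4/STAT6 list 2 fell without IL4 replicate 1, and none without untreated replicate 1 or IL4 replicate 2.

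Cell cycle genes fell together with IL4. Of 50 measured, 40 fell and none rose, or 44 adjusted over the list alone, with a median log2 change of -0.55 (adjusted p = 2.2e-17, and adjusted p = 0.066 with an estimated correlation). The mitotic kinases CDK1 and TTK changed by -0.89 (SE 0.11) and -0.99 (SE 0.15). NF-kB and inflammation genes rose in 11 of 25 cases and fell in 4, or 5 adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.051 with an estimated correlation). The complement gene C3 rose from 73.3 ± 2.34 to 353 ± 27.8 CPM and the cytokine gene IL11 rose 8.34-fold. NRF2 targets fell in 14 of 34 cases and rose in 4, or 16 and 4 adjusted over the list alone (adjusted p = 0.0089, and adjusted p = 0.20 with an estimated correlation). Without untreated replicate 3, only 7 NF-kB genes and 2 NRF2 targets rose. The 4 fallen NF-kB genes became 2 without untreated replicate 1 or Compound A replicate 2, and 1 without untreated replicate 2 or 3, IL4 replicate 2 or control siRNA replicate 3. GPX2, a glutathione peroxidase, changed by -0.69 (SE 0.09) and NQO1, a quinone reductase, by -0.38 (SE 0.04).

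Unfolded protein and stress response genes rose in 11 of 38 cases and fell in 1, or 12 and 1 adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.26 with an estimated correlation). Hypoxia and glycolysis genes rose in 11 of 35 cases and fell in 2, or 12 and 2 adjusted over the list alone (adjusted p = 0.027, and adjusted p = 0.36 with an estimated correlation). With a correction for GC content, added after the data were seen, neither list passed, at adjusted p = 0.067 and 0.082. The remaining lists did not pass as groups. Of 26 eicosanoid genes 5 rose and 9 fell, 7 and 9 adjusted over the list alone (adjusted p = 0.72). The median was -0.03 and the mean 0.21, and ALOX5, another lipoxygenase gene, rose 2.79-fold. Of 27 cholesterol genes 3 rose and 6 fell, 4 and 7 adjusted over the list alone (adjusted p = 0.72). Of 23 fatty acid genes 7 rose and 3 fell by either adjustment (adjusted p = 0.26), the desaturase SCD from 1999 ± 100 to 2804 ± 118 CPM. Of 21 genes of PPAR targets and fatty acid oxidation, 4 rose and 3 fell by either adjustment (adjusted p = 0.31), with PPARG 1.34-fold up and the kinase gene PDK4 at -1.20 (SE 0.08). Of 29 ferroptosis genes 9 rose and 4 fell, 11 and 5 adjusted over the list alone (adjusted p = 0.31), with the lipid peroxidase GPX4 1.70-fold up. Member counts again rested on single libraries. Without untreated replicate 2, 3 eicosanoid genes rose and 5 fell, 3 cholesterol genes fell and 1 fatty acid gene fell. Without IL4 replicate 2, 3 eicosanoid genes and 1 cholesterol gene rose. Without IL4 replicate 3, 3 eicosanoid genes rose and 2 stress response genes fell, and without untreated replicate 3 1 fatty acid gene fell. In the hypoxia list 4 fell without IL4 replicate 1, and 1 without untreated replicate 1 or 2 or IL4 replicate 2. No stress response gene fell in the fits without untreated replicate 1 or 2, IL4 replicate 2, or any Compound A, control siRNA or ALOX15 siRNA library.

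Of 10 liver X receptor targets, 2 rose with IL4, or 3 with 1 fallen adjusted over the list alone (adjusted p = 0.73), the median being 0.01 and the mean -0.02. Of 29 p53 targets 6 rose and 3 fell by either adjustment (adjusted p = 0.97); the median log2 change was -0.05 although camera pointed up. Of 15 aryl hydrocarbon receptor and xenobiotic genes 1 rose and 6 fell, 7 adjusted over the list alone (adjusted p = 0.30), with a median of -0.14 and a mean of 0.14. Of 20 mucin and goblet cell genes 4 rose and 3 fell by either adjustment (adjusted p = 0.70), the median being -0.09 and the mean 0.48. Of 8 alveolar genes 3 rose and 1 fell by either adjustment (adjusted p = 0.13). Without IL4 replicate 1, 3 p53 targets and 2 aryl hydrocarbon receptor genes rose, 6 mucin genes fell and no alveolar gene fell. Without untreated replicate 3, 3 p53 targets rose and none fell, 1 fell without untreated replicate 1 or 2, and 5 without IL4 replicate 3. Without untreated replicate 1, 3 aryl hydrocarbon receptor genes fell. One liver X receptor target rose without untreated replicate 2, IL4 replicate 2 or 3, Compound A replicate 1 or 3, control siRNA replicate 1 or any ALOX15 siRNA library. One fell without untreated replicate 1, IL4 replicate 3 or Compound A replicate 1. Over all 12795 genes tested, 2925 changed with IL4 by edgeR's quasi-likelihood test, 1435 up and 1490 down, and 358 of them by at least 2-fold (275 up, 83 down). The balance of directions was not stable: without untreated replicate 2, 1181 rose and 801 fell, with upper-quartile scaling 1562 and 1251, and with DESeq2 1346 and 1165. With only these 6 libraries in the fit, 1467 genes changed, 891 up and 576 down.

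**Figure D3:**
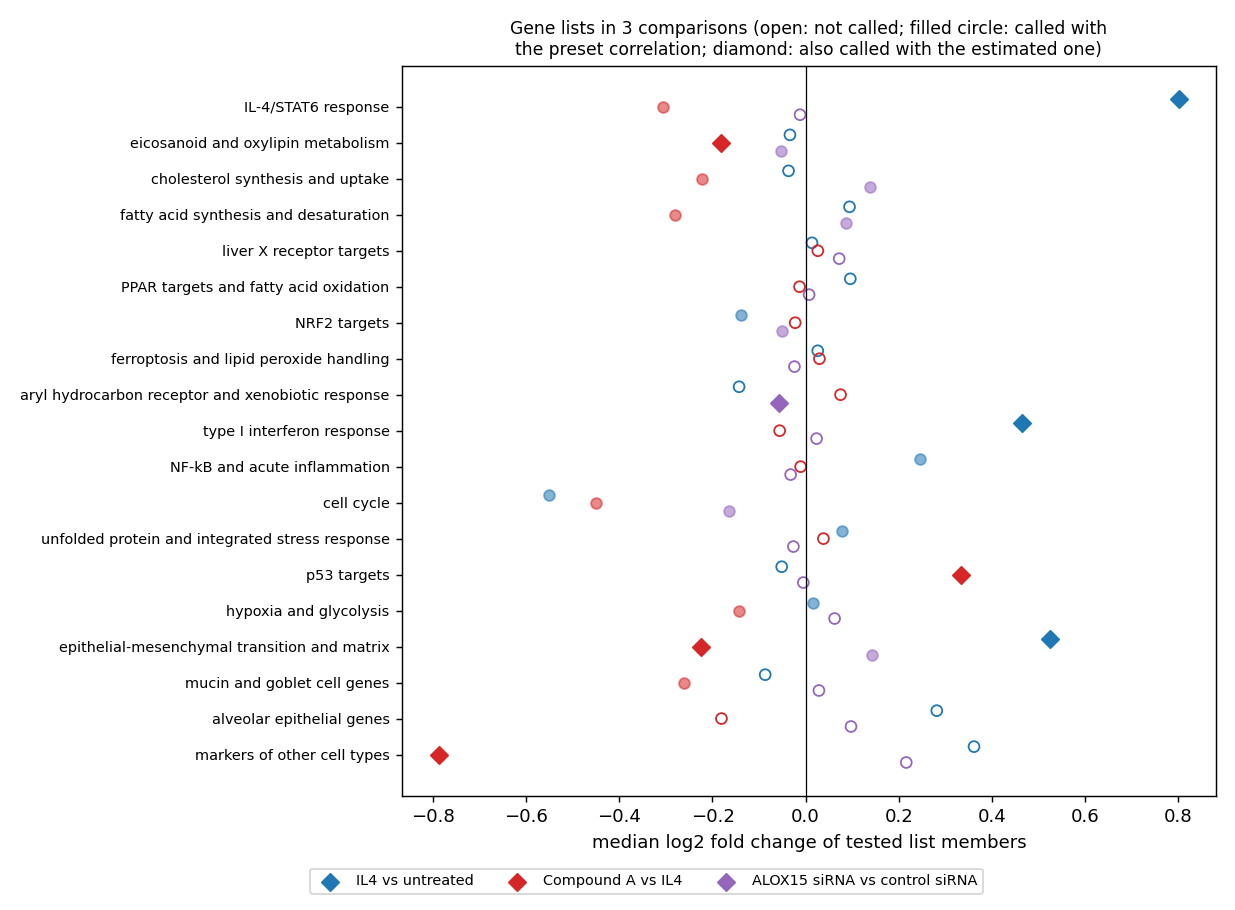
Median log2 fold change of the measured members of each of 19 gene lists (x axis) in 3 comparisons (colours). Open symbols did not pass, filled circles passed with the preset correlation, and diamonds passed also with an estimated one. Markers of other cell types lie at -0.79 with Compound A, and the IL-4/STAT6 list lies at 0.80 with IL4. The eicosanoid list did not pass with ALOX15 siRNA once ALOX15 was left out of it.

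The second comparison asked what Compound A changed in IL4-treated cells. HMOX1 (chromosome 22, 35380361 to 35394214), the heme-degrading enzyme, rose from 145 ± 20.4 to 280 ± 6.69 CPM (SD, n = 3), a log2 change of 0.95 (SE 0.07, adjusted p = 2.6e-07). AKAP12 (chromosome 6, 151239999 to 151358557), a scaffold for protein kinase A, rose from 84.7 ± 8.94 to 173 ± 12.2 CPM. Among p53 targets, GDF15, a stress-induced cytokine, rose 1.63-fold and ZMAT3, an RNA-binding protein, 1.68-fold. Among the largest falls by the fixed rule that also passed against control siRNA were those in UBD, a ubiquitin-like modifier, with a log2 change of -2.17 (SE 0.46), and in the cell junction genes CLDN4 with -1.92 (SE 0.36) and CDH16 with -1.71 (SE 0.29). The complement gene C3 changed by -0.70 (SE 0.06). Unlike these, CCL26 was at 99.998 ± 3.58 CPM with Compound A and 98.3 ± 18.8 CPM with IL4 alone (log2 0.03, SE 0.10, adjusted p = 0.89).

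Because IL4 replicate 1 stood apart from its group mates, Compound A was also set against the control siRNA libraries, a comparison added after the data were seen, in which the groups differ by the control siRNA too. The labels do not say whether cells without siRNA were mock transfected, nor whether cells without Compound A received its vehicle, so its effects may include those of a vehicle. Against control siRNA, HMOX1 changed by 0.90 (SE 0.07, adjusted p = 6.9e-07), AKAP12 by 0.91 (SE 0.08), GDF15 by 0.72 (SE 0.13) and ZMAT3 by 0.53 (SE 0.12). UBD changed there by -1.77 (SE 0.49), CLDN4 by -1.51 (SE 0.38), CDH16 by -1.53 (SE 0.30) and C3 by -0.68 (SE 0.06). All of these passed in that comparison, the highest adjusted p being 0.039 for UBD.

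Cell cycle genes fell with Compound A in 31 of 50 cases and none rose, or 36 adjusted over the list alone, below the level IL4 had already lowered (adjusted p = 4.1e-17, and adjusted p = 0.066 with an estimated correlation). The replication genes MCM5 and GINS2 changed by -1.11 (SE 0.17) and -1.24 (SE 0.22). Of 29 p53 targets 15 rose and none fell, or 24 adjusted over the list alone (adjusted p = 1.2e-10, and adjusted p = 0.0084 with an estimated correlation). Cholesterol genes fell in 15 of 27 cases and none rose, or 16 fell and 1 rose adjusted over the list alone (adjusted p = 5.2e-06, and adjusted p = 0.11 with an estimated correlation). Fatty acid genes fell in 13 of 23 cases and 1 rose, or 13 and 2 adjusted over the list alone (adjusted p = 0.00089, and adjusted p = 0.23 with an estimated correlation). Without Compound A replicate 2, 7 cholesterol and 7 fatty acid genes fell, without Compound A replicate 3, 7 cholesterol genes, and without IL4 replicate 1, 7 fatty acid genes. Of fatty acid genes 3 rose without IL4 replicate 2 or 3, and of cholesterol genes 2 rose without IL4 replicate 3. The desaturase FADS2 changed by -0.58 (SE 0.10). Fatty acid synthase, FASN, changed by -0.77 (SE 0.17), but its call was lost without IL4 replicate 1 or Compound A replicate 2, with an adjusted p of up to 0.057.

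Matrix and transition genes fell in 15 of 39 cases and 1 rose, or 17 and 4 adjusted over the list alone (adjusted p = 3.3e-05, and adjusted p = 0.036 with an estimated correlation). COL1A1 changed by -1.11 (SE 0.16) and the collagen COL6A1 by -0.88 (SE 0.12). Beside them, 4 of the 6 measured markers of other cell types fell, with a median of -0.79 (adjusted p = 0.00084, and adjusted p = 0.036 with an estimated correlation), by either adjustment, that over all genes or adjusted over the list alone. The 4 were COL1A1, LUM, a matrix proteoglycan, CD68, a lysosomal glycoprotein, and TUBB3, a tubulin whose reads were shared with other genes in all 15 libraries. LUM, CD68 and TUBB3 did not pass against control siRNA. Eicosanoid genes fell in 7 of 26 cases and 1 rose by either adjustment, that over all genes or adjusted over the list alone (adjusted p = 0.0049, and adjusted p = 0.046 with an estimated correlation, or 0.013 and 0.060 without ALOX15). Without Compound A replicate 2, 3 eicosanoid genes fell, and without Compound A replicate 3, 4 eicosanoid and 9 matrix genes. No eicosanoid gene rose without untreated replicate 2, IL4 replicate 1 or 2, any Compound A library, control siRNA replicate 1 or ALOX15 siRNA replicate 2 or 3, and 2 matrix genes rose without IL4 replicate 1. GGT1, which processes glutathione conjugates, changed by -0.70 (SE 0.09), with reads shared in all 15 libraries.

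Mucin and goblet cell genes fell in 6 of 20 cases, or 8 adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.051 with an estimated correlation), among them the glycosyltransferase GALNT5 at -0.65 (SE 0.14). MUC5AC, also among them, changed by -0.63 (adjusted p = 0.023), and by -0.49 against control siRNA, where it did not pass (adjusted p = 0.11). IL-4/STAT6 genes fell in 4 of 20 cases and 1 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.28 with an estimated correlation). That call was lost without IL4 replicate 1 (adjusted p = 0.071). Hypoxia and glycolysis genes fell in 12 of 35 cases and 2 rose, or 14 and 5 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.33 with an estimated correlation). With GC correction that list did not pass (adjusted p = 0.082). NRF2 targets went both ways, 6 up and 11 down of 34, or 7 and 12 adjusted over the list alone (adjusted p = 0.67), although HMOX1 is among them. Without IL4 replicate 1, 3 mucin genes, 2 IL-4/STAT6 genes and 7 NRF2 targets fell, and without Compound A replicate 3 these were 3, 2 and 3. Mucin genes fell in 3 cases without Compound A replicate 1, and NRF2 targets in 2 without Compound A replicate 2. No IL-4/STAT6 gene rose without IL4 replicate 1 or Compound A replicate 2 or 3. Of hypoxia genes 7 rose without IL4 replicate 3, and 1 without untreated replicate 3, IL4 replicate 2 or any Compound A, control siRNA or ALOX15 siRNA library. The interferon list had 1 up and 1 down of 34 by either adjustment, that over all genes or adjusted over the list alone (adjusted p = 0.50). There none rose without Compound A replicate 2, and 2 fell without untreated replicate 1, IL4 replicate 3 or Compound A replicate 1.

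The same lists were tested for Compound A against control siRNA, adjusted over the 19 lists there, after the data were seen. Of p53 targets 7 rose (adjusted p = 1.1e-12, and adjusted p = 0.0026 with an estimated correlation), and 19 cell cycle genes fell (adjusted p = 1e-15 and 0.043), 9 cholesterol genes (1.2e-08 and 0.043) and 8 fatty acid genes (9.1e-06 and 0.059). So did 8 matrix genes (3.9e-06 and 0.014), 7 eicosanoid genes (0.00087 and 0.014), 3 mucin genes (0.0017 and 0.043) and 1 marker of other cell types (0.0091 and 0.043). Of hypoxia genes 6 fell (0.038 and 0.36), and of interferon genes 1 rose and 2 fell (0.038 and 0.088). The IL-4/STAT6 list, with 1 fallen, did not pass (0.085), nor did NRF2 targets, with 3 up and 7 down (0.26). With IL4 replicate 1 out of the fit 20 p53 targets rose, and 27 cell cycle, 18 cholesterol, 13 fatty acid, 15 matrix, 7 mucin, 12 hypoxia, 3 interferon and 2 IL-4/STAT6 genes, 11 NRF2 targets and 2 markers fell. Beside them rose 3 hypoxia genes, 6 NRF2 targets, 2 matrix genes, from 1, and 1 fatty acid and 1 mucin gene, from none.

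Compound A changed 1846 genes against IL4 alone by edgeR's quasi-likelihood test, 813 up and 1033 down, and 90 by at least 2-fold (10 up, 80 down). Against control siRNA 675 genes changed, 591 of them among the 1846, or 1646 with IL4 replicate 1 out of the fit and 1290 with GC correction. With only the 6 libraries of the comparison in the fit, 380 changed. The count rested on single libraries: it was 782 (299 up) without Compound A replicate 2, 971 (387 up) without Compound A replicate 3 and 3030 (1496 up) without IL4 replicate 3. It was 1266 (512 up) without IL4 replicate 1, the library that stood apart.

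The third comparison asked what knockdown of ALOX15 changed, against control siRNA and with IL4 in both groups. Besides ALOX15 itself, PTGS2 (chromosome 1, 186671791 to 186680427) fell from 391 ± 36.5 to 271 ± 9.77 CPM (SD, n = 3), a log2 change of -0.53 (SE 0.08, adjusted p = 0.0033). PLA2G4A fell from 124 ± 6.18 to 86.6 ± 1.46 CPM (log2 -0.52, SE 0.07, adjusted p = 0.00087). CYP24A1, which inactivates vitamin D, fell from 586 ± 13.3 to 402 ± 12.7 CPM, and ABCG2, a drug efflux pump, from 63.3 ± 3.66 to 42.7 ± 1.34 CPM. SCD (chromosome 10, 100347124 to 100364834) rose from 2730 ± 30.8 to 3865 ± 166 CPM (log2 0.50, SE 0.06, adjusted p = 0.00018), and INSIG1, which holds back sterol synthesis, rose 1.46-fold. SLC26A2, a sulfate transporter, rose 1.61-fold.

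Of the genes that fell most, SERPINI1, a neuronal serine protease inhibitor, changed by -1.22 (SE 0.17), CFI, a complement protease, by -0.73 (SE 0.13) and RBFOX3, a splicing factor, by -0.69 (SE 0.09). The cysteine protease inhibitor CST1 changed by -0.78 (SE 0.09), with reads shared with related genes in 14 libraries. Of those that rose, NPTX1, a pentraxin, changed by 0.77 (SE 0.10), EFEMP1, a matrix protein, by 0.75 (SE 0.12) and NAV1, a neuron navigator, by 0.74 (SE 0.12). Each of the genes named so far in this comparison kept its call when any 1 library was left out. The matrix gene TNC, which had the highest log2 change of the genes that passed, at 1.25 (SE 0.26, adjusted p = 0.026), lost its call without any of the 6 siRNA libraries, with an adjusted p of up to 0.18. CCL26 had a log2 change of 0.26 (SE 0.10, adjusted p = 0.41), CISH of -0.02, MUC5AC of 0.26 and HPGD, which inactivates prostaglandins, of 0.21, and none of them passed.

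Of 15 aryl hydrocarbon receptor and xenobiotic genes 4 fell and none rose, by either adjustment, that over all genes or adjusted over the list alone (adjusted p = 0.0013, and adjusted p = 0.036 with an estimated correlation). They were CYP24A1, ABCG2, ALDH3A1, an aldehyde dehydrogenase at -0.46 (SE 0.07), and the cytochrome gene CYP2S1 at -0.51 (SE 0.11). CYP2S1 lost its call without untreated replicate 2 or 3, control siRNA replicate 1 or 2, or any Compound A or ALOX15 siRNA library, with an adjusted p of up to 0.22. Of 26 eicosanoid genes 3 fell by either adjustment, that over all genes or adjusted over the list alone, namely ALOX15, the target itself, PTGS2 and PLA2G4A. The list passed only with ALOX15 in it (adjusted p = 0.018), and then not with an estimated correlation (adjusted p = 0.066). Without ALOX15 it did not pass, by a test added after the data were seen (adjusted p = 0.13). Cholesterol genes had a median of 0.14, with 1 of 27 up, or 2 up and 1 down adjusted over the list alone (adjusted p = 0.00021, and adjusted p = 0.21 with an estimated correlation). Fatty acid genes had a median of 0.09, with 1 of 23 up, or 5 adjusted over the list alone (adjusted p = 0.0023, and adjusted p = 0.26 with an estimated correlation). Without IL4 replicate 1, 4 cholesterol genes rose and 1 fell, and 3 fatty acid genes rose.

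Matrix and transition genes rose in 4 of 39 cases, or 11 with 4 fallen adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.077 with an estimated correlation). The 6 markers of other cell types had a median of 0.22 beside them, and none passed by either adjustment (adjusted p = 0.20). None of the 50 cell cycle genes passed over all genes and 4 fell adjusted over the list alone, with a median of -0.16 (adjusted p = 4.1e-07, and adjusted p = 0.26 with an estimated correlation). NRF2 targets had a median of -0.05 and 1 of 34 fell, or 3 adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.22 with an estimated correlation). The IL-4/STAT6 list had 2 of 20 down, ALOX15 and CST1, or 1 up and 2 down adjusted over the list alone (adjusted p = 0.31). Without IL4 replicate 1, 9 matrix genes rose, 4 cell cycle genes and 4 NRF2 targets fell, and 2 IL-4/STAT6 genes rose. Without IL4 replicate 3, 1 cell cycle gene and 2 NRF2 targets fell and 1 IL-4/STAT6 gene rose. Matrix genes rose in 2 cases without control siRNA replicate 1 or ALOX15 siRNA replicate 2, and in 1 without control siRNA replicate 3 or ALOX15 siRNA replicate 1 or 3.

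With the knockdown 89 genes changed by edgeR's quasi-likelihood test, 40 up and 49 down, and 8 of them by at least 2-fold (1 up, 7 down). The count was 36, 51 and 39 without control siRNA replicate 1, 2 or 3, and 52, 46 and 36 without ALOX15 siRNA replicate 1, 2 or 3. Of these 12, 20, 13, 20, 16 and 14 rose. It was 273 without IL4 replicate 1, a library of neither group that adds to the shared estimate of the spread. It was 322 with only these 6 libraries in the fit and 320 with GC correction. In these last 3 fits 147, 171 and 170 rose and 126, 151 and 150 fell, so the balance of directions turned.

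Control siRNA against IL4 alone asked what the control siRNA itself changed. No gene passed by edgeR's quasi-likelihood test, and DESeq2 called 2. By the edgeR test 628 genes (4.91%) had an unadjusted p under 0.05, about the share that arises where nothing changed. With GC correction 1 gene passed, and also 1 without untreated replicate 3. PTGS2 had a log2 change of 0.13 (SE 0.08), CCL26 of -0.14 (SE 0.10), CISH of -0.39 (SE 0.18) and MUC5AC of -0.14 (SE 0.16), each with an adjusted p of 0.898 or above. As groups, the 50 cell cycle genes had a median of -0.11 (adjusted p = 0.00014, and adjusted p = 0.36 with an estimated correlation), with 1 fallen adjusted over the list alone. The 6 markers of other cell types had a median of -0.40 (adjusted p = 0.0023, and adjusted p = 0.046 with an estimated correlation) and did not pass without IL4 replicate 1 (adjusted p = 0.055). The IL-4/STAT6 list had a median of -0.12 (adjusted p = 0.037, and adjusted p = 0.35 with an estimated correlation) and did not pass without IL4 replicate 1 (adjusted p = 0.84) or without ALOX15 in it (adjusted p = 0.094). None of the members of these last 2 lists passed alone, over all genes or adjusted over the list alone.

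Whether Compound A and the knockdown differed was tested gene by gene as the difference of their log2 changes. TNC had a difference of -2.47 (SE 0.38, adjusted p = 0.00057), LUM of -2.80 (SE 0.63) and CLDN4 of -2.35 (SE 0.47), and each was lower with Compound A. SERPINI1 had a difference of 1.71 (SE 0.22) and the homeobox gene HOXA5 of 2.15 (SE 0.48). These use Compound A against IL4 alone. Against control siRNA its change did not pass in TNC (-0.49, adjusted p = 0.40, from -1.23), LUM (-1.31, adjusted p = 0.17, from -2.02), SERPINI1 (0.08, adjusted p = 0.79, from 0.49) or HOXA5 (0.03, adjusted p = 0.98, from 1.34). ALOX15 itself had 2.62 (SE 0.55), the knockdown being the stronger. In all, 658 genes differed by edgeR's quasi-likelihood test, 248 higher and 410 lower with Compound A. The list of p53 targets differed upward with Compound A, 9 members of 29 passing (adjusted p = 8.7e-09, and adjusted p = 0.0085 with an estimated correlation), and cholesterol genes downward, 10 of 27 passing (adjusted p = 8.7e-09, and adjusted p = 0.040 with an estimated correlation). Matrix genes differed downward with 11 of 39 members and upward with 1 (adjusted p = 1.2e-07, and adjusted p = 0.0085 with an estimated correlation), beside 4 of the 6 markers of other cell types downward (adjusted p = 0.00023, and adjusted p = 0.014 with an estimated correlation). These list tests of the difference were added after the data were seen. The count of genes was 1142 (508 higher) without IL4 replicate 3, and 337 (115 higher) and 404 (143 higher) without Compound A replicate 2 or 3. It was 414 (149 higher) and 392 (139 higher) without control siRNA replicate 1 or 3, and 1314 (534 higher) with GC correction. Without ALOX15 siRNA replicate 1, 2 or 3 it was 405 (147 higher), 402 (148 higher) and 448 (158 higher).

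Genes called in both comparisons were few: 25 went opposite ways and 13 the same way, where independent lists would share 6.34 and 6.498. Across all genes tested no general opposition was seen: the log2 changes had a Pearson correlation of -0.12 and a Spearman correlation of 0.045. Signs were opposite in 49.6% of the 1846 genes changed by Compound A and 60.7% of the 89 changed by the knockdown. With GC correction the Spearman correlation was -0.050 and these shares were 55.3% and 56.9%. SCD changed by -0.36 (SE 0.06) with Compound A and 0.50 (SE 0.06) with the knockdown and INSIG1 by -0.36 (SE 0.09) and 0.55 (SE 0.08). MMD, a membrane protein first found in macrophages, changed by 0.47 (SE 0.10) and -0.61 (SE 0.10), RBFOX3 by 0.62 (SE 0.08) and -0.69 (SE 0.09), and CYP24A1 by 0.28 (SE 0.06) and -0.55 (SE 0.06). PTGS2 changed by 0.26 (SE 0.08, adjusted p = 0.039) with Compound A and -0.53 (SE 0.08) with the knockdown. The difference passed for all 25, which their choice by opposite calls made all but certain, so it adds no support. Against control siRNA the Compound A change did not pass in MMD (0.28, adjusted p = 0.093) or PTGS2 (0.13, adjusted p = 0.38). Among those named next, it did not pass there in ALOX15 or CFI (-0.41, adjusted p = 0.053). In the same direction went ALOX15, CST1, PLA2G4A, with -0.25 (SE 0.07) and -0.52 (SE 0.07), CFI, with -0.49 (SE 0.12) and -0.73 (SE 0.13), and SLC26A2, with 0.40 (SE 0.10) and 0.69 (SE 0.10). Against control siRNA, Compound A shared 9 genes of the same and 16 of the opposite direction with the knockdown, but that comparison has the control siRNA libraries in common with it, which favours the same direction. There it was 54 the same and 49 opposite with IL4 replicate 1 out of the fit, and 54 each with GC correction, so the balance depended on the comparator and the fit. Against IL4 alone the 13 became 30 without IL4 replicate 1, beside 62 opposite, 23 without IL4 replicate 3, 7 without Compound A replicate 2, 7 without Compound A replicate 3, 8 without control siRNA replicate 3 and 8 without ALOX15 siRNA replicate 3. With GC correction it was 47, beside 92 opposite.

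**Figure D4:**
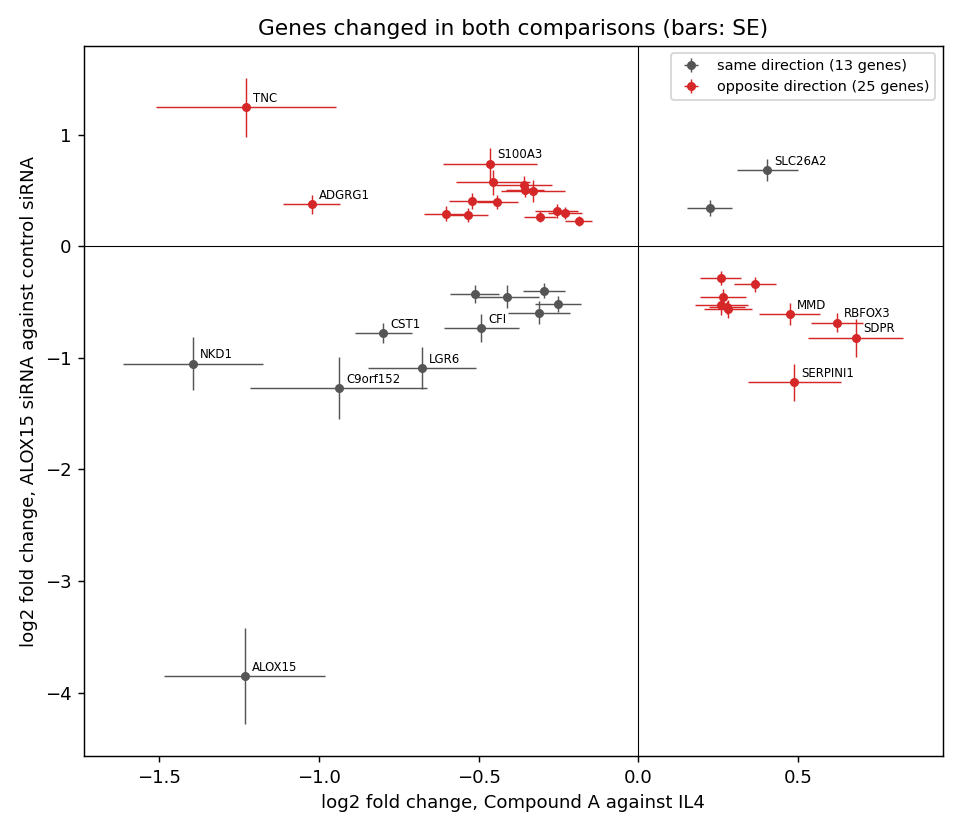
Log2 fold change with Compound A against IL4 (x axis) and with ALOX15 siRNA against control siRNA (y axis) for the 38 genes that changed in both, with SE bars. Of these, 25 genes lie in the opposite quadrants, TNC among them at -1.23 and 1.25, and 13 in the same ones, with ALOX15 at -1.23 and -3.85.

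Of the 2925 genes that IL4 changed, 546 moved back with Compound A and 245 moved further the same way, where independent lists would share 211 in each case. UBD, CEACAM7, DUOX2 and COL1A1 were among those that rose with IL4 and fell with Compound A, CEACAM7 by -1.40 (SE 0.28), and AKAP12 and UNC5D among those that did the reverse. Both comparisons use the 3 IL4 libraries, which cannot be split into parts of 2 libraries each, so part of the excess may come from them. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of -0.36 and a covariance of -0.0608. Unchanged groups simulated with shared libraries gave means of -0.49 and -0.0312, the covariance with an SD of 0.00596 and a lowest value of -0.0409. No gene moved back in any of 20 simulations. Since the simulated groups held no IL4 effect, neither that count nor the correlation is a like baseline. Against control siRNA, which shares no library with IL4 against untreated, 221 genes moved back and 141 moved on, with 76.7 and 77.6 for independent lists. The covariance was then -0.0208. Without IL4 replicate 1 those numbers were 362 back, 308 on and -0.0118, with a Spearman correlation of 0.00323, and with GC correction 376, 282 and -0.0126. Whether the opposite movement across all genes goes beyond the shared libraries is therefore open. Of the genes that moved back, 206 did so against both comparators, and 168 of these also did so without IL4 replicate 1 and with GC correction. The calls of these 168 against control siRNA rest on no shared library, though they may include an effect of the control siRNA. The 546 became 1105 without IL4 replicate 3, 281 without Compound A replicate 2, 331 without Compound A replicate 3 and 119 with only the libraries of each comparison in its fit. Against IL4 alone, 376 moved back and 246 moved on without IL4 replicate 1, and 611 and 421 with GC correction.

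With the knockdown, 14 of the IL4-changed genes moved back and 55 moved further in the direction of IL4, where independent lists would share 10.2 in each case and no library is shared. Those moving back included ALOX15, CST1 and CFI, and those moving on included PTGS2 and PLA2G4A, lowered by both, and SCD, INSIG1 and TNC, raised by both. The 14 became 35 without IL4 replicate 1, beside 147 moving on. They became 7 without control siRNA replicate 1, 9 without ALOX15 siRNA replicate 2 and 7 without ALOX15 siRNA replicate 3. They became 44 with GC correction, beside 185 moving on, and 33 with only the libraries of each comparison in its fit.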

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

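The tests of depth, of the IL4 response in single libraries, of shared libraries, of GC content in the last 2 patterns and of movement along the IL4 response were chosen after the result was seen, while the GC test of IL4 replicate 1 and the regroupings of libraries were written down before their results were seen.

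A closer look was asked of results in which the effects of Compound A and of ALOX15 siRNA differed by a test of the difference. That held for 658 genes. It also held for all 25 genes called in opposite directions, which the choice of those genes made all but certain. By the fixed rule C8orf44-SGK3 ranked first, but it had no count in any IL4 or ALOX15 siRNA library, so its fitted difference depends on the prior count and is not given. It also had counts that were not whole in 7 libraries and lost its call in 13 of the 15 fits with 1 library left out. The next highest differences were 2.62 for ALOX15, 2.25 for NPHS1, 2.15 for HOXA5 and 1.71 for SERPINI1. The lowest were -2.83 for PRR15L, -2.83 for SLC9A3, -2.80 for LUM, -2.47 for TNC and -2.35 for CLDN4. Against control siRNA, of these genes only CLDN4 passed for Compound A. NPHS1 lost its call in 8 of those 15 fits (adjusted p up to 0.086), SLC9A3 in 4 (up to 0.072) and PRR15L in 3 (up to 0.052). Of 100 drawn regroupings of the 12 libraries, the labelled one gave the most genes, 658, and the next gave 618. Of the 8 others that kept Compound A and IL4 libraries as labelled, 2 gave 615 and 618 genes and 6 gave 113 to 216, and the 91 that mixed them gave at most 6.

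IL4 replicate 1 lay apart from its group mates, with an SD of log2 differences across genes of 0.332. A GC content trend could account for part of this, since correction lowered the SD to 0.216, but that stayed above the highest of 12 libraries in other groups, 0.169. Lower depth did not account for it: 6 libraries had a lower total, and their highest SD was 0.177. Another strength of the IL4 response stays open: IL4-raised genes differed by a median of 0.0226 with GC correction, within the -0.0207 to 0.0337 of the siRNA libraries, but by 0.0912 without it, outside their -0.0323 to 0.0276. What else set this library apart was not tested.

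Of the genes changed by IL4, 65.2% had the opposite sign with Compound A. Unchanged groups simulated with shared libraries gave 67.2% over all genes. They held no IL4 effect, so that share is not a like baseline and decides nothing here. Against control siRNA, with no shared library, the opposite share was 58.9%. It was 50.6% without IL4 replicate 1 and 52.5% with GC correction. The shared IL4 libraries alone push toward opposite signs. In the comparison with no shared library the covariance was -0.0208, below the -0.0108 to 0.0113 of the 9 other splits. Without IL4 replicate 1 it was -0.0118, within their -0.0180 to 0.00617. With correction for a GC content trend it was -0.0126, below their -0.00916 to 0.00899 by less than their SD, 0.00559. For the movement across all genes, shared libraries, a GC content trend and an effect of Compound A cannot be told apart here. The opposite movement is a hypothesis found and tested on the same data, and the value of -0.0208 may include an effect of the control siRNA, which differs between those groups.

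Genes changed by both IL4 and ALOX15 siRNA mostly went further in the direction of IL4, 79.7% of them. A GC content trend did not account for it, as the share after correction was 80.8%. A stronger IL4 response in the ALOX15 siRNA cultures could not be settled: genes changed at least 2-fold by IL4 moved on by a median of 0.127, against at most 0.0783 in other splits, while IL-4/STAT6 genes other than ALOX15 had a median of -0.00714. That explanation and an effect of the knockdown itself cannot be told apart here.

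For each pairwise comparison the 6 libraries allow 10 splits, too few for a share under 0.05. The labelled split gave 2925, 1846 and 89 genes with IL4, Compound A and ALOX15 siRNA, the highest other giving 0 each time, so that 1 of 10 reached the count. For control siRNA all 10 of 10 gave 0. Lists called within a comparison numbered 8 against a highest other of 5 with IL4, 10 against 8 with Compound A, 7 against 2 with ALOX15 siRNA (the eicosanoid list among the 7 only with ALOX15 in it) and 2 against 1 with control siRNA, reached by 1 of 10 each time. Of the overlaps, 14 genes moved back with ALOX15 siRNA, 546 moved back with Compound A and 13 went alike, each against 0 in every other split, again 1 of 10.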

How the results depend on the processing

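No call of a named gene, list or ALOX15 level turned its direction, and genes not named were not checked for this. The balance of genes up and down did turn with IL4 (1435 to 1490, or 1181 to 801 without untreated replicate 2). It also turned with ALOX15 siRNA (40 to 49, or 147 to 126 without IL4 replicate 1). ALOX15 stayed between 4.69 and 6.33 with IL4, -1.36 and -1.13 with Compound A, -4.07 and -3.59 with ALOX15 siRNA and -0.63 and -0.45 with control siRNA when any library was left out, on the log2 scale. Gene counts then ran from 1982 to 3307 (IL4), 782 to 3030 (Compound A), 36 to 273 (ALOX15 siRNA), 0 to 1 (control siRNA) and 337 to 1142 (difference), and overlaps from 7 to 35 (back with ALOX15 siRNA), 281 to 1105 (back with Compound A) and 7 to 30 (alike). Over all named genes and all fits with 1 library left out, 354 calls were weaker, 6 stronger and 3555 unchanged. These numbers include genes that had not passed and fits without a library of another group. Of the named genes that had passed, 9 of 85 with IL4 lost their call in at least 1 of these fits. So did 40 of 99 with Compound A, 24 of 42 with ALOX15 siRNA and 4 of 10 for the difference. Fitting only the compared groups gave 1467, 380 and 322 genes with IL4, Compound A and ALOX15 siRNA, and 33 and 119 moved back with ALOX15 siRNA and Compound A. These counts fell with IL4 and Compound A and rose with ALOX15 siRNA. The spread is then set by those libraries alone. Leaving out IL4 replicate 1 by itself raised the ALOX15 siRNA count from 89 to 273, so its share in the spread could account for part of that rise. Why the other counts fell was not tested. At least a 2-fold change left 358, 90, 8 and, for the difference, 96 genes, and overlaps of 1, 27 and 2, as a stricter threshold must. GC correction gave 320 genes with ALOX15 siRNA, 1 with control siRNA and 1314 for the difference, 44 moved back with ALOX15 siRNA and 47 alike. Compound A against control siRNA gave 675 genes, ALOX15 at -0.68 and 221 moved back, and with IL4 replicate 1 out of that fit 1646 genes, ALOX15 at -0.68, 362 moved back against 308 moving on, and 54 alike against 49 opposite, a turned balance (9 against 16 with it in). DESeq2 called 2 genes with control siRNA. Beyond the construction named, the cause was not tested. With an estimated correlation 9 of 28 list calls were left. Scaling, filters and rounding changed at most 12 of 261 calls of named genes each. Fitting only the compared groups changed more of them, with 63 weaker, 2 stronger and 196 unchanged. For Compound A against control siRNA, ALOX15 apart, 55 calls of named genes were weaker and 50 unchanged. With IL4 replicate 1 out of that fit these were 33 and 72. With the replicate block, 21 genes went alike, and the other block counts stayed within 1.5 times (3363, 2508, 128, 0 and 969 genes). Whether equal replicate numbers mark paired samples is unknown, as the labels do not say. Of 30 same-number pairs 8 correlated over 0.1, from -0.13 to 0.29, and 7 of 15 libraries correlated best with their own number. The block raised every gene count except that for control siRNA. Depth limits genes such as ALOX15, with 0 to 44 counts per library.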

Other observations

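Among the 11 of 35 hypoxia and glycolysis genes that rose with IL4 were HK1, a hexokinase, 2.42-fold, PFKFB4, which sets the rate of glycolysis, 2.69-fold and EGLN3, an oxygen sensor, 2.82-fold. CA9 was 1 of the 2 that fell, and as a group the list did not pass with an estimated correlation (adjusted p = 0.36) or with GC correction (adjusted p = 0.082). TNFAIP6, which binds hyaluronan, rose 9.53-fold, TAGLN, an actin-binding protein of contractile cells, 4.45-fold, and CDKN1A, an inhibitor of cell division, 1.45-fold. ALB, the gene of albumin, changed by -2.20 (SE 0.52) and the ephrin receptor gene EPHB3 by -1.84 (SE 0.23).

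Among genes that IL4 raised and Compound A lowered against both comparators were several outside the naming rule, chosen after their values were seen. The keratin gene KRT6A changed by 3.39 (SE 0.36) with IL4 and -1.03 (SE 0.28) with Compound A against control siRNA, and the basement membrane collagen COL17A1 by 1.90 (SE 0.19) and -0.93 (SE 0.18). The vitamin D receptor gene VDR changed by 1.60 (SE 0.16) and -0.66 (SE 0.15), FBN2, a microfibril protein, by 2.02 (SE 0.07) and -0.71 (SE 0.06), and CLDN2, a tight junction protein, by 0.81 (SE 0.09) and -0.83 (SE 0.09).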
